A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

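The data are 6 one-colour (Cy3) arrays of total RNA from Saccharomyces cerevisiae, 3 labelled xylose at 9 h and 3 labelled glucose at 3 h, each at 50 g/L of sugar, with replicates 1 to 3 numbered in the sample titles. Groups were taken from the titles. Per the file headers and the submitters' processing notes, the authors scanned the arrays and extracted spot intensity values with Agilent Feature Extraction 10.1.1.1; per the file headers, the processed intensity is background-subtracted and detrended, with a surrogate value for the dimmest spots, and an extended dynamic range scan was used. The deposited flags used were those for spots well above background, saturated, non-uniform or outlying in their population. A deposited table of log2 values accompanies the scanner files. How the authors made it is not given in the sources used here; set against the scanner files, 82.6% of its values equalled log2 of the processed signal less 1 constant per array within 0.001, and that constant was the array's 75th percentile, so its scale is log2, its direction that of the signal and it holds no centring per gene. The column medians of that table were -1.25, -1.23 and -1.38 for xylose replicates 1 to 3 and -1.26, -1.26 and -1.41 for glucose replicates 1 to 3.

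Control spots and spots marked non-uniform or outlying were left out, between 727 and 1722 of 43792 spots per array, and no spot was saturated. The log2 processed signal of the remaining spots was reduced by the array's 75th percentile, and the 7 spots of each probe were averaged. A probe counted as well above background on an array when more than 0.5 of its spots were, and probes so on at least 3 of 6 arrays were tested, 5907 of 6256. Each gene had 1 probe. Gene symbols came from a reference table of assembly R64 matched by locus tag, which named 5756 of 6256 probes and 5621 of the 5907 tested; the others keep the systematic name of the array. No coordinates are printed, since the files name no genome build. A gene not well above background on any array of a group is given as a bound: the brighter group's mean against the mean, per array of the dim group, of the higher of the dimmest level among probes well above background and the probe's own.

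Signal at the 75th percentile lay between 1407 and 3871 units, the share of probes well above background between 92.3% and 95.6%, and the median coefficient of variation over the spots of a probe between 4.11% and 9.31%. Xylose replicates 1 and 2 differed by a median absolute deviation of 0.12 (log2), against 0.67 and 0.71 for the other xylose pairs and 0.03 expected from the spots. Repeat arrays of 1 RNA can also differ by more than the spots do, so this leaves open whether they are separate samples; they were kept as 2 samples because the labels list them so, with their average as an added alternative. Slide 1 held replicates 1 and 2 of both sugars and slide 2 replicate 3 of both.

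Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, called at an adjusted p under 0.05), with sugar as the only term. A gene was alike in both sugars when its 95% confidence interval lay within a log2 difference of 1 either way. Before the data were examined, 33 gene lists were fixed: hexose transporters, galactose genes, disaccharide genes, glycolysis and ethanol formation, xylose and xylulose enzymes, pentose phosphate pathway, TCA cycle, glyoxylate cycle and gluconeogenesis, respiratory chain and ATP synthase, mitochondrial ribosomal proteins, beta-oxidation and peroxisome, glycerol and acetate metabolism, trehalose and glycogen, heat shock proteins, oxidative stress defence, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, amino acid synthesis, nitrogen catabolite repression, purine synthesis, phosphate starvation, iron uptake, ergosterol synthesis, anaerobic genes, histones, cell cycle G1/S, mitosis, a-cell, alpha-cell and haploid mating genes, meiosis and quiescence, and a list of commonly used promoters that was described gene by gene. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, with an estimated correlation and fry beside it. Of the 33 lists 17 were called, 9 up and 8 down, 1 of them with an estimated correlation, and fry, which tests whether the genes of a list move 1 way on balance, called 13. Unlike camera, fry called the galactose (adjusted p = 0.0342) and haploid mating lists (0.0215). It did not call the disaccharide (0.0944), mitochondrial ribosomal (0.212), cytosolic ribosomal (0.556), G1/S (0.212), mitosis (0.241) and meiosis lists (0.273). The same lists gave 21 calls without glucose replicate 2, 18 with the replicate block, 16 with the slide block and 12 within slide 1. Calls lost with an estimated correlation cannot be put down to correlation alone. Ergosterol and a-cell mating genes had estimates of -0.012 and -0.084, under the preset. Their camera adjusted p still rose from 0.00771 to 0.152 and from 4.4e-04 to 0.115.

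Genes are named by a rule written before the data were examined: the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, the 3 largest called changes of each list and the largest called change against its median, the promoter genes changed at least 2-fold or alike, and every measured hexose transporter and xylose or xylulose enzyme. Some of the genes that the rule names are not reported here. Others are said to be chosen after their values were seen; MPH2 in the disaccharide list, DAN1 and the genes of glucose replicate 2 were named in that way, as were GAL10, HIS3, CYC1, HSP12, HXK1, SSA1, RPS2, ENO2 and ALD6.

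Whether the replicate numbers pair the samples was checked by the correlation, across genes, of deviations from the group means between arrays of the same number, which was 0.40 for number 1, 0.22 for number 2 and 0.71 for number 3. On slide 1, arrays of different number and sugar correlated alike, at 0.41 for xylose 2 with glucose 1 and 0.25 for xylose 1 with glucose 2, so there the number adds nothing to the slide. All 3 pairs exceed a cut of 0.1, on which the numbers were treated as pairs, though not in the main fit. That cut cannot show pairing, since the arrays of different number on slide 1 exceed it as well. The titles call each number a run of the fermentation but do not say whether a run was shared between the sugars, and number 3 coincides with slide 2. The main fit has no block. Blocked values are given where they changed a call or moved a count by over 1.5 times.

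The alternatives tried were normexp background correction (offset 50, on the median spot signal) with quantile normalization, median centring, quantile normalization, centring on the spike-in controls, the authors' table of log2 values, no filter on dim probes, a filter on all 6 arrays, a trended and robust variance, the replicate number or the slide as a block, and leaving out each array in turn. Alternatives added after seeing the data were keeping the outlying spots, averaging xylose replicates 1 and 2, and slide 1 alone. The procedure was tested on simulated data for 5907 genes, drawn independently for each gene and array with the gene's spread within groups. Of 100 genes changed by a log2 difference of 1 it recovered 7, of 100 changed by 2 it recovered 63, and 2 unchanged genes were called. Shared slide effects, correlated genes, near-identical arrays and an outlying array were not simulated, so the simulated rates need not hold for these data. The simulated intervals held the true value for 94.6% of genes, and 99.9% of genes called alike truly were. The latter share was largely fixed in advance, since all genes but the changed ones had no true difference. Of 33 simulated lists the 1 shifted list was called, with 1 other. Genes of the simulated lists were not correlated, while the estimated correlation of the real cytosolic ribosomal protein genes was 0.70.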

Results

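Gene expression in the budding yeast Saccharomyces cerevisiae was measured on 6 one-colour Agilent arrays, 3 from cells kept for 9 h in fermentation medium with 50 g/L xylose and 3 from cells kept for 3 h in the same kind of medium with 50 g/L glucose. Sugar and time differed together, so each difference below is that of xylose at 9 h against glucose at 3 h and cannot be assigned to either. A further label field of the glucose samples reads 9 h; the 3 h of their titles, time labels and design text was used. The strain is not given in the sources used here. The titles number the replicates as fermentation runs, but whether these were separate cultures is not stated. The p-values therefore measure only the spread between these samples, which may be technical. Of 6256 probes, 1 per gene, between 5777 and 5979 were well above background on an array, and 5907 genes were tested. The number of arrays limits the precision.

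The 6 arrays did not fall evenly into their groups. Xylose replicates 1 and 2 correlated at r = 0.993 across genes, and both correlated with xylose replicate 3 at 0.953 to 0.963. Genes are not independent replicates, so these correlations describe the arrays and test nothing. Glucose replicates 1 and 3 correlated at 0.958, whereas glucose replicate 2 correlated with them at 0.868 and 0.837. In glucose replicate 2, 41 genes lay more than 8-fold from their level on every other array, against 0 to 3 genes on each of the others. LEU2 and MET17, enzymes of leucine and of methionine synthesis that laboratory strains often lack, were well above background in that array at log2 levels of 0.34 and 4.57 relative to the array's 75th percentile, and lay between -9.07 and -7.88 on the other arrays. The asparaginase genes ASP3-1 to ASP3-4 were not well above background in glucose replicate 2, with ASP3-1 at -8.55, and ASP3-1 lay between 2.87 and 3.99 on the others. HXT1, the low-affinity glucose transporter, stood at 3.46 in glucose replicate 2 against -1.55 and -0.73 in glucose replicates 1 and 3. Counts over all genes and of promoter genes are therefore given with all 6 arrays and without glucose replicate 2. Leaving out each array in turn was planned before the data were examined, but this array was singled out after its values were seen. Counts of genes called within lists are with all 6 arrays unless stated.

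**Figure D1:**
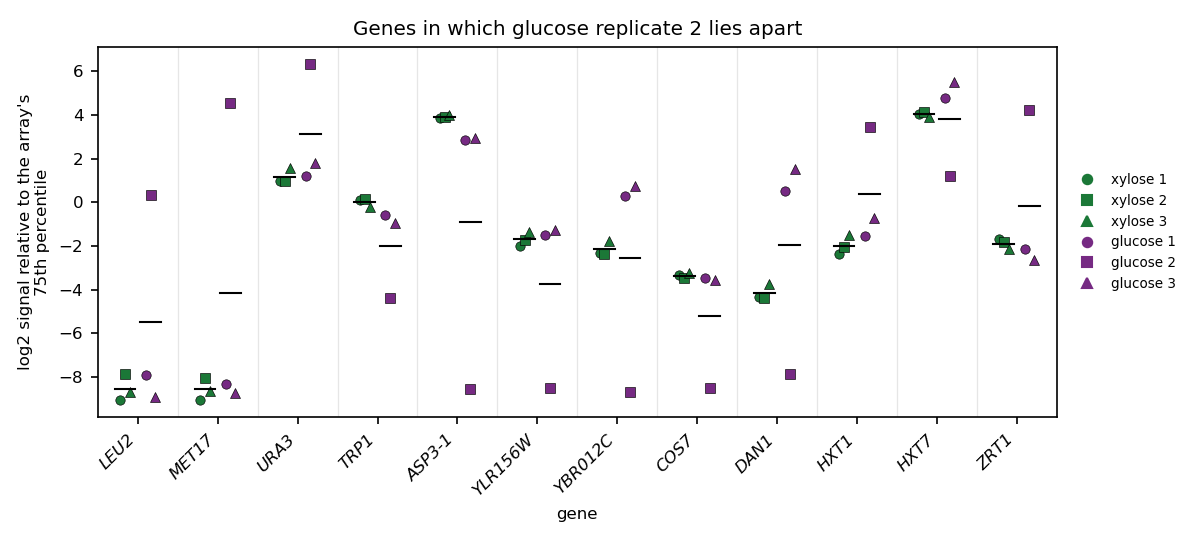
Levels of 12 genes, chosen after their values were seen, on each of the 6 arrays, as log2 signal relative to the array's 75th percentile (y axis); points are arrays, coloured by sugar and shaped by replicate number, and black bars are group means. Glucose replicate 2 (purple square) lies outside the other arrays for every gene drawn, with LEU2 at 0.34 and ASP3-1 at -8.55.

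The study's title asks which promoters serve during cultivation on xylose, and the comparison of the sugars answers which transcripts differed. Among the highest rises in xylose was the formate dehydrogenase gene FDH1 (YOR388C, log2 difference 6.90 ± 0.84, SE, n = 3 against 3), whose probe may not tell it from similar sequences. The glucose level of FDH1 was well above background on 1 of 3 arrays, glucose replicate 2, so the difference rests on dim signals; without that array FDH1 was at least 127-fold higher in xylose. Also among them were GRE1 (YPL223C), a hydrophilin of dry and osmotic stress, at 24.6-fold, NCE103 (YNL036W), the carbonic anhydrase, at 18.9-fold, and MPC3 (YGR243W), a subunit of the mitochondrial pyruvate carrier, at 17.0-fold. YNL120C was not well above background on any glucose array and was at least 5.58-fold higher in xylose, the bound being set by the dimmest probes well above background on each glucose array. The acetate transporter gene ADY2 (YCR010C) rose 13.0-fold. The near-identical maltase genes MAL12 (YGR292W) and MAL32 (YBR299W) rose 12.2-fold and 10.5-fold, and TMA10 (YLR327C) rose 8.74-fold. The glycerol transporter gene STL1 (YDR536W), well above background on 2 of 3 glucose arrays, rose 9.95-fold. Adjusted p-values of these genes from limma lay between 0.00204 for GRE1 and 0.0238 for STL1.

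With all arrays, the gene higher in glucose by the largest margin was HXT3 (YDR345C), a low-affinity glucose transporter, at 19.2-fold (log2 difference -4.27 ± 0.51, limma adjusted p = 0.0148). Next came SSA2 (YLL024C), a cytosolic Hsp70 chaperone, at 17.2-fold. Its near-identical copy SSA1 differed by -1.07 with an adjusted p = 0.641, and by -2.26 (adjusted p = 0.0227) without glucose replicate 2. The polyamine exporter gene TPO2 (YGR138C) was 17.0-fold higher, the histidine synthesis gene HIS4 (YCL030C) 13.5-fold, the purine synthesis gene ADE17 (YMR120C) 13.3-fold, and the glucose transporter gene HXT4 (YHR092C) 12.5-fold. The order of these genes changed without glucose replicate 2. Log2 differences were then -4.97 for SSA2, -4.43 for HIS4, -4.30 for HXT4, -3.94 for ADE17, -3.66 for HXT3 and -3.46 for TPO2. PHO84 (YML123C), the high-affinity phosphate transporter, was 11.8-fold higher in glucose. Its log2 difference without glucose replicate 2 was -4.10, larger in size than those of ADE17, HXT3 and TPO2. SET6 (YPL165C) was 8.57-fold higher in glucose and IMD2 (YHR216W), an IMP dehydrogenase of GTP synthesis, 8.56-fold. In the same direction lay the cell wall gene UTR2 (YEL040W) at 7.79-fold, the cyclin gene PCL1 (YNL289W) at 7.60-fold, and MIG2 (YGL209W), a repressor acting at high glucose, at 7.50-fold. SET6 and IMD2 were well above background on 2 of 3 xylose arrays. Adjusted p-values of these 12 genes lay between 0.00228 for ADE17 and 0.0405 for SSA2. With the replicate number as a block, the adjusted p was 0.0570 for HXT4 and 0.0644 for IMD2, and the other genes named among the largest rises and falls stayed under 0.05. With xylose replicates 1 and 2 averaged as 1 sample, only GRE1, NCE103, MPC3, YNL120C, ADY2, MAL12, ADE17, UTR2 and PCL1 of them stayed called. The limma adjusted p of the others then ran from 0.0751 for FDH1 to 0.170 for SSA2.

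Over all genes, 149 of the 5907 tested (2.52%) passed limma's threshold of 0.05 after Benjamini-Hochberg adjustment, 84 higher and 65 lower in xylose, and each of the 149 differed at least 2-fold. Without glucose replicate 2 the count was 682, 348 higher and 334 lower, of which 548 differed at least 2-fold, and all 149 genes were among the 682 with the same direction. Leaving out xylose replicate 1, 2 or 3 gave 12, 12 and 13 genes, and leaving out glucose replicate 1 or 3 gave 28 and 53. With the replicate number as a block 310 genes were called, 163 higher and 147 lower. With the slide as a block 690 were called, 379 higher and 311 lower. Whether xylose replicates 1 and 2 are separate samples stays open, and their average as 1 sample left 12 genes. Within slide 1, which held 2 arrays per sugar, limma called 0 genes, with 987 at an unadjusted p under 0.05. Slide 2 held 1 array per sugar, which allows no test. All 149 genes had the same sign within both slides. This had to be so and is no replication, because the groups did not overlap for any of the 149. Centring on the spike-in controls moved the median of all genes from 0.02 to -0.70 and gave 25 genes higher and 134 lower, so directions are relative to the bulk of the transcripts. On that scale 66 of the 149 genes stayed called. For the named genes whose call or direction it changed, limma's adjusted p there followed the size of the difference, whatever the gene's own spread. It was 0.0748 for PUT4 (2.07), 0.0650 for GPP1 (-2.11), 0.0286 for XKS1 (-2.35) and 0.000891 for HXT1 (-3.09). Calls gained or lost on that scale are thus close to a cut on size. Among the genes named here, spike-in centring ended the calls of the rises NQM1, TKL2, SDH1, SDH4, ADH2, ACS1, ICL1, COX4, COX5A, COX8, SSA3, CTT1, TRX3, NUG1, PUT4, FIT2, MF(ALPHA)1, ARO9 and XBP1 and of the fall GPP1. The groups did not overlap for 1386 genes, 23.5% of those tested, where chance gives 10% for exchangeable arrays, which arrays that deviate together within slides are not. The 95% interval lay within 2-fold either way for 2030 genes (34.4%), here called alike. That number was 735 and 836 without xylose replicate 1 or 2, 1196 without glucose replicate 1, and 2263 without glucose replicate 2. It was 3331 with the replicate block, 3349 with the slide block and 2303 within slide 1.

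Among the 17 hexose transporters and glucose sensors measured, HXT3 and HXT4 fell and none rose. Of the others, HXT2, a high-affinity transporter, differed by 1.03 ± 0.31, HXT17 by 1.09 ± 0.55 and the sensor gene SNF3 by 0.97 ± 0.46, none past the threshold. HXT15 and HXT16, well above background on 1 of 3 glucose arrays, differed by 1.60 ± 0.50 and 1.60 ± 0.71. Without glucose replicate 2, HXT15 (adjusted p = 0.00439), HXT16 (0.00540), HXT17 (0.00830) and HXT9 (0.0488) passed. HXT15 and HXT16 were then not well above background on any glucose array, with bounds of at least 3.65-fold and 1.99-fold. HXT1 differed by -2.37 ± 1.19 with all arrays and by -0.84 without glucose replicate 2. On the spike-in scale it passed as lower (limma adjusted p = 0.000891). That value followed the size of its difference there (-3.09) and not the spread between its arrays. The near-identical high-affinity transporter genes HXT6 and HXT7 differed by 1.14 ± 1.08 and 0.20 ± 1.03. Without glucose replicate 2 they differed by -0.26 and -1.12; HXT6 stood in that array at 0.16 against 3.70 to 4.45 on the other arrays. The values of HXT5, HXT8, HXT9, HXT10 and GAL2 were 0.42, 0.11, 0.38, 0.66 and 0.60, which turn negative, as does that of HXT7, with spike-in centring. Those of HXT12 and the sensor gene RGT2 were -0.13 and -0.28. As a list the transporters had a median of 0.42 (0.19 without glucose replicate 2) and a mean of -0.05, and camera, run with a preset correlation of 0.01, gave an adjusted p = 0.487.

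**Figure D2:**
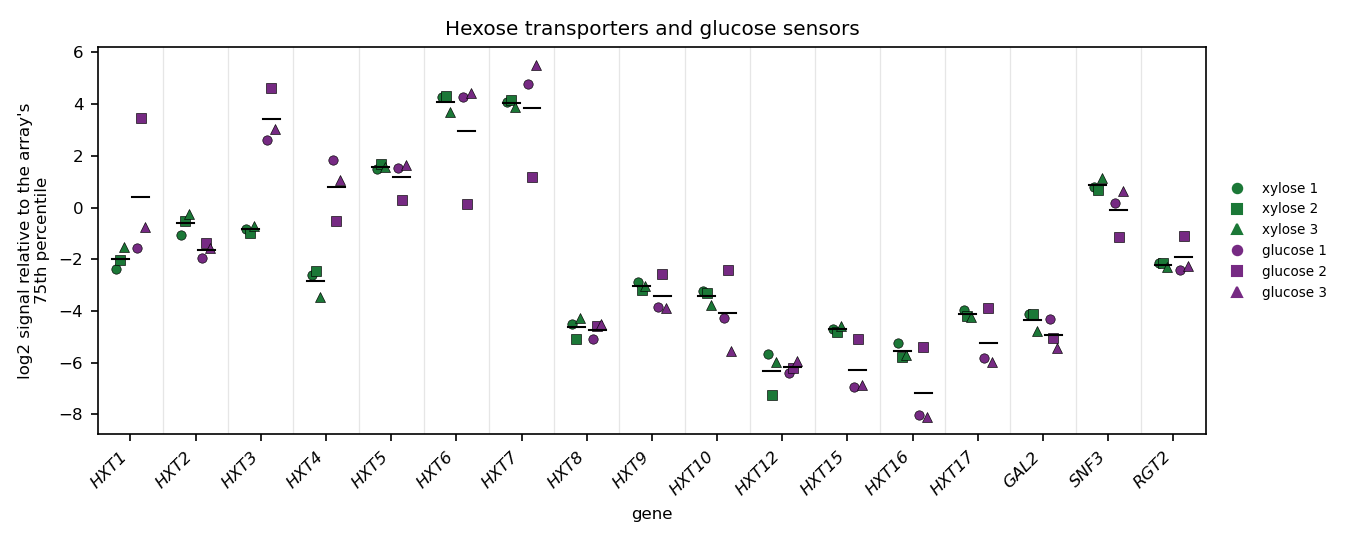
Levels of the 17 measured hexose transporter and sensor genes on each array, as log2 signal relative to the array's 75th percentile (y axis); points are arrays, coloured by sugar and shaped by replicate number, and black bars are group means. HXT3 and HXT4 were lower on all 3 xylose arrays, and glucose replicate 2 lies apart for HXT1, HXT6 and HXT7.

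None of the 9 measured genes for enzymes of xylose and xylulose passed the test with all arrays. XKS1, the xylulokinase, differed by -1.63 ± 0.48 (limma adjusted p = 0.148), its level reaching 5.19 in glucose replicate 2 against 2.23 to 3.87 on the others. On the spike-in scale XKS1 passed as lower (0.0286), a value that followed the size of its difference there (-2.35) and not its spread. The sorbitol dehydrogenase genes SOR1 and SOR2, near-identical copies well above background on 1 of 3 glucose arrays, differed by 1.46 ± 0.85 and 1.51 ± 0.92, that array being glucose replicate 2. Without it neither was well above background in glucose, and they were at least 3.76-fold (adjusted p = 0.0135) and 3.63-fold (0.0128) higher in xylose. GRE3, an aldose reductase that acts on xylose, differed by -0.74 ± 0.43, YPR1 by -0.46, YDL124W by -0.45. The xylitol dehydrogenase gene XYL2 differed by 0.37, YJR096W by 0.39 and GCY1 by 0.60, all of which turn negative with spike-in centring. The list had a median of 0.37 and a mean of 0.12, while camera ranked it down with an adjusted p = 0.908; without glucose replicate 2 the median was 0.09 and camera ranked it up (0.675). In the pentose phosphate pathway 2 of 11 genes rose, NQM1 by 2.03 ± 0.36 and TKL2 by 1.72 ± 0.25, both minor copies of transaldolase and transketolase, and the list did not pass (median 0.50, adjusted p = 0.190). Its median was 0.02 without glucose replicate 2.

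Glycolysis and ethanol formation (21 genes) had a median of -0.18 and did not pass with all arrays (camera adjusted p = 0.0577). Over the alternatives its adjusted p ran from 0.00396 with normexp to 0.860 without glucose replicate 3, where the median was -0.10. The list passed as lower with the replicate block (0.0231), with the slide block (0.0223), without xylose replicate 3 (0.00553) and without glucose replicate 2 (0.00566). It also passed with outlying spots kept (0.0473), with quantile normalization (0.0211) and with normexp. It did not pass without xylose replicate 1 (0.265) or with spike-in centring (0.180), among others. Its adjusted p with an estimated correlation was 0.594 with all arrays and 0.362 without glucose replicate 2. Its 1 called gene, HXK2 for hexokinase 2, fell to 0.344 of its glucose level. The galactose genes (9) had a median of 0.60, or -0.12 with spike-in centring, and an adjusted p = 0.0505, and none of them was called. That list passed as higher with the replicate block (0.0478), without xylose replicate 1 (0.0285) or 2 (0.0193) and without glucose replicate 3 (0.0313), and in 5 further settings with values up to 0.0495, that of median centring. It did not pass without xylose replicate 3 (0.204), glucose replicate 1 (0.0860) or glucose replicate 2 (0.0794). The adjusted p with an estimated correlation was 0.233 with all arrays and 0.222 without glucose replicate 2. Fry called the galactose list with all arrays (adjusted p = 0.0342).

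Genes for disaccharide use (14) shifted up by camera, with a median of 0.93 and an adjusted p = 0.0237, and 0.458 as the adjusted p with an estimated correlation. The maltase genes MAL12 and MAL32 rose, and MPH2 and MPH3, permeases for maltose and other alpha-glucosides, fell; MPH3 fell by 1.91 on the log2 scale. Adjusted over the list alone, 9 genes rose and 3 fell. The adjusted p was 0.0825 with the replicate block and 0.0892 with the slide block. It was 0.0656 without glucose replicate 1 and 0.104 without glucose replicate 3. The median was 0.78 within slide 1 (adjusted p = 0.220) and 1.12 within slide 2.

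Of 38 genes of the respiratory chain and ATP synthase 16 rose and none fell, against 25 rises and 1 fall without glucose replicate 2. Adjusted over the list alone with all arrays, 35 rose. The cytochrome c oxidase subunits COX4, COX5A and COX8 rose by 2.14 ± 0.39, 2.11 ± 0.40 and 2.02 ± 0.28, COX5A having an adjusted p = 0.0534 with the replicate block. The list's median was 1.43, with 1.44 within slide 1 and 1.38 within slide 2, and its camera adjusted p = 1.9e-26. It was the 1 list of the 17 called that held with an estimated correlation (adjusted p = 0.0164). Without glucose replicate 2, and so with fewer arrays, that value was 0.104, where camera with the preset correlation gave 2.0e-16.

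The glyoxylate cycle and gluconeogenesis list (20) shifted up with a median of 1.12 (camera adjusted p = 1.6e-07), or 1.68 without glucose replicate 2; the adjusted p = 0.152 with an estimated correlation. Its 5 rises, 10 adjusted over the list alone, included ADY2, the alcohol dehydrogenase gene ADH2 (2.53 ± 0.33) and the acetyl-CoA synthetase gene ACS1 (2.31 ± 0.39). In the TCA cycle list (18) the succinate dehydrogenase genes SDH1 and SDH4 rose by 1.41 ± 0.23 and 1.26 ± 0.21, and 6 genes rose adjusted over the list alone. With outlying spots kept SDH4 differed by 0.86 (adjusted p = 0.295). The TCA list shifted up with a median of 0.46 (camera adjusted p = 0.00250), which is -0.26 with spike-in centring; the adjusted p = 0.155 with an estimated correlation. Within slides 1 and 2 the medians were 1.04 and 1.73 for the glyoxylate list, and 0.34 and 0.53 for the TCA list.

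Genes of fatty acid beta-oxidation and the peroxisome (20) shifted up with a median of 0.55, or -0.18 with spike-in centring (camera adjusted p = 2.6e-04); the adjusted p = 0.233 with an estimated correlation. None was called, and 2 rose adjusted over the list alone. Mitochondrial ribosomal proteins (52) shifted up with a median of 0.37, or -0.35 with spike-in centring (camera adjusted p = 2.6e-04), with no gene called. The adjusted p was 0.494 with an estimated correlation and 0.212 with fry. That list's median was 0.23 and its camera adjusted p = 0.0990 without glucose replicate 2. Within slides 1 and 2 the medians were 0.47 and 0.56 for the first list and 0.48 and 0.20 for the second. Glycerol, acetate and aldehyde metabolism (20, median 0.32, or 0.03 without glucose replicate 2, adjusted p = 0.204) had 1 rise, STL1, and 1 fall, the glycerol phosphatase gene GPP1 (-1.39 ± 0.24), with 6 rises adjusted over the list alone.

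**Figure D3:**
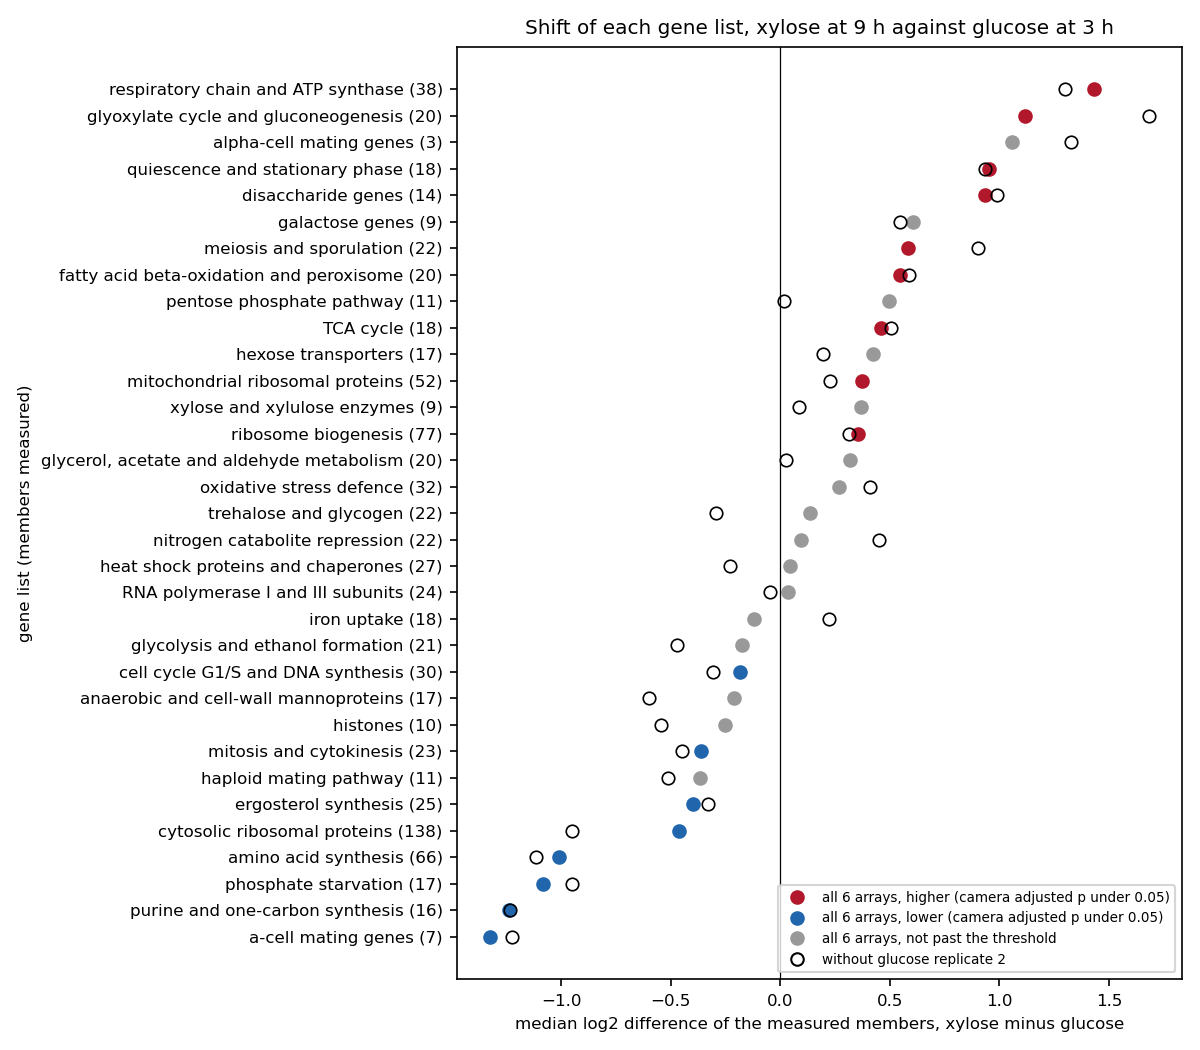
Median log2 difference, xylose minus glucose (x axis), of the measured members of each of the 33 gene lists (y axis, members in brackets); filled points are all 6 arrays, red or blue where camera's adjusted p was under the threshold, and open points leave out glucose replicate 2. With all 6 arrays the respiratory chain lies highest at 1.43 and a-cell mating genes lowest at -1.32, an order that changes without glucose replicate 2; with spike-in centring the median of all genes is -0.70 and list medians between 0 and about that size turn negative.

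Of 66 amino acid synthesis genes 13 fell and none rose, against 30 falls and 1 rise without glucose replicate 2. Adjusted over the list alone with all arrays, 28 fell. The largest falls were HIS4, the argininosuccinate lyase gene ARG4 (-2.72 ± 0.52) and HIS1 (-2.43 ± 0.33), ARG4 having an adjusted p = 0.0626 with the replicate block and 0.0514 with the slide block. HIS3, LEU2 and MET17, also listed, were not tested. HIS3 was not well above background on any array, and LEU2 and MET17 were so in glucose replicate 2 alone. The list's median was -1.01, with -0.90 within slide 1 and -1.07 within slide 2 (camera adjusted p = 1.6e-16); the adjusted p = 0.0778 with an estimated correlation. In purine and one-carbon synthesis (16) 5 genes fell, 10 adjusted over the list alone, among them ADE17, ADE3 (-1.66 ± 0.29) and ADE2 (-1.60 ± 0.23), ADE3 having an adjusted p = 0.0784 with quantile normalization. The median there was -1.24, with -1.12 and -1.34 within the slides (camera adjusted p = 6.7e-07); the adjusted p = 0.155 with an estimated correlation. Without glucose replicate 2, 8 genes of the purine list fell and 1 rose.

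Genes of the phosphate starvation response (17) shifted down with a median of -1.08 (camera adjusted p = 6.7e-07), with -1.07 and -0.98 within slides 1 and 2; the adjusted p = 0.0778 with an estimated correlation. PHO84 fell, and 5 genes fell adjusted over the list alone. Ergosterol synthesis (25) shifted down with a median of -0.40 (camera adjusted p = 0.00771, and 0.0697 with spike-in centring), with -0.41 and -0.42 within the slides; the adjusted p = 0.152 with an estimated correlation. No ergosterol gene was called, and 4 fell and 1 rose adjusted over the list alone.

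Cytosolic ribosomal protein genes (138) shifted down with a median of -0.46 (camera adjusted p = 5.9e-06), while no single gene passed. The adjusted p was 0.594 with an estimated correlation and 0.556 with fry. Without glucose replicate 2, 49 of them fell and the median was -0.95; without glucose replicate 1 the median was -0.21 and the adjusted p = 0.0573, and without glucose replicate 3 they were -0.22 and 0.0499. Within slide 1 the median was -0.19 (adjusted p = 0.0797) and within slide 2 it was -0.97. Genes of ribosome biogenesis (77) shifted the other way with a median of 0.36, or -0.36 with spike-in centring (camera adjusted p = 5.7e-05), with 0.44 and 0.17 within slides 1 and 2; the adjusted p = 0.233 with an estimated correlation. Of these 1 gene rose, NUG1 (1.16 ± 0.22), and none adjusted over the list alone. Subunits of RNA polymerases I and III (24) had a median of 0.03, or -0.05 without glucose replicate 2, and an adjusted p = 0.908.

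Nitrogen catabolite repression genes (22, median 0.09, adjusted p = 0.198) held 1 rise, the proline permease gene PUT4 (2.79 ± 0.46), and the list passed as higher without glucose replicate 2 (0.0200), where the adjusted p = 0.165 with an estimated correlation. The iron uptake list (18), with a median of -0.12 and a mean of 0.13, had an adjusted p = 0.908 and 1 rise, the mannoprotein gene FIT2 (2.27 ± 0.34). Its median was 0.22 and its adjusted p = 0.108 without glucose replicate 2, with 5 rises and 1 fall.

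The quiescence and stationary phase list (18) shifted up with a median of 0.95 (camera adjusted p = 6.0e-06), with 1.39 and 0.77 within slides 1 and 2; the adjusted p = 0.115 with an estimated correlation. Its 3 rises, 6 adjusted over the list alone, were GRE1, the aromatic aminotransferase gene ARO9 (1.58 ± 0.30) and XBP1, a repressor of starved cells (1.46 ± 0.24). ARO9 had an adjusted p = 0.0554 with the replicate block. Oxidative stress genes (32, median 0.27, adjusted p = 0.0999) held 2 rises, the cytosolic catalase gene CTT1 (2.04 ± 0.30) and the mitochondrial thioredoxin gene TRX3 (1.63 ± 0.26), and the list passed as higher without glucose replicate 2 (0.0340), where the adjusted p = 0.173 with an estimated correlation. Heat shock proteins and chaperones (27, median 0.04, adjusted p = 0.979) held 1 rise, SSA3 (2.15 ± 0.35), and 1 fall, SSA2, both of them Hsp70 genes; without glucose replicate 2 the list's median was -0.23 and its adjusted p = 0.120. Trehalose and glycogen genes (22, median 0.13, adjusted p = 0.427) held no call. The direction of that list rested on single arrays: it passed as higher without glucose replicate 3 (0.0499) and was ranked lower without glucose replicate 2, with a median of -0.29 and an adjusted p = 0.0982. With all arrays the adjusted p = 0.867 with an estimated correlation. The anaerobic and cell-wall mannoprotein list (17, median -0.21, adjusted p = 0.291) passed as lower without glucose replicate 2 (0.00410), in which DAN1 was not well above background, and with spike-in centring (0.0112). Its adjusted p with an estimated correlation was 0.152 without glucose replicate 2 and 0.594 with all arrays.

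No gene of the cell cycle lists was called with all 6 arrays. Without glucose replicate 2, 6 genes of the G1/S and DNA synthesis list and 2 of the mitosis and cytokinesis list fell. The G1/S and DNA synthesis list (30) shifted down with a median of -0.19 (camera adjusted p = 0.00813), with -0.15 within slide 1 (0.0899) and -0.31 within slide 2; the adjusted p = 0.458 with an estimated correlation. Its median ran from -0.31 without glucose replicate 2 and -0.29 without xylose replicate 1 to -0.11 without glucose replicate 1, and the adjusted p = 0.113 without glucose replicate 3. The mitosis and cytokinesis list (23) shifted down with a median of -0.36 (camera adjusted p = 0.0372), with -0.26 within slide 1 (0.174) and -0.54 within slide 2; the adjusted p = 0.484 with an estimated correlation. That call was lost without xylose replicate 2 (adjusted p = 0.0818), glucose replicate 1 (0.0885) or glucose replicate 3 (0.276). It was also lost with normexp (0.0501), quantile normalization (0.0553), spike-in centring (0.103) and xylose replicates 1 and 2 averaged (0.0574). Histone genes (10) had a median of -0.25 and an adjusted p = 0.348; the median was -0.54 without glucose replicate 2 and -0.08 without glucose replicate 1.

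The a-cell mating genes (7), active in cells of mating type a, shifted down with a median of -1.32 (camera adjusted p = 4.4e-04), with -1.20 and -1.37 within slides 1 and 2; the adjusted p = 0.115 with an estimated correlation. None was called, and 5 fell adjusted over the list alone. Of 3 alpha-cell genes measured (median 1.06, adjusted p = 0.159) the pheromone gene MF(ALPHA)1 rose by 1.33 ± 0.26, well above background on 1 of 3 glucose arrays, and the list passed as higher without glucose replicate 2 (0.0197), where the adjusted p = 0.222 with an estimated correlation. The call of MF(ALPHA)1 ended with 5 settings besides spike-in centring that kept all arrays as separate samples, with an adjusted p = 0.292 for normexp. The haploid mating list (11, median -0.37, camera adjusted p = 0.112, fry adjusted p = 0.0215) held 1 fall, the mating-type endonuclease gene HO (-1.68 ± 0.27). Meiosis and sporulation genes (22) shifted up with a median of 0.58, or -0.14 with spike-in centring (camera adjusted p = 0.0259), and 2 rose adjusted over the list alone. Its median was 0.90 without glucose replicate 2, where 7 genes rose and 1 fell, against none called with all arrays. The median was 0.24 without glucose replicate 3. The adjusted p = 0.494 with an estimated correlation, 0.0556 with the slide block, 0.0878 without glucose replicate 1 and 0.263 without glucose replicate 3. It was 0.0791 with normexp, 0.0734 with spike-in centring and 0.0641 with no filter on dim probes. Within slide 1 the median was 0.38 (0.281) and within slide 2 it was 0.87.

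For the genes whose promoters are in common use in yeast engineering, 41 of 42 were measured, GAL10 being too dim, and 3 differed at least 2-fold past the threshold. ADH2 rose 5.77-fold and ICL1, the isocitrate lyase gene of the glyoxylate cycle, 3.00-fold in xylose, while HXK2 was 2.91-fold higher in glucose. The adjusted p of ICL1 was 0.0589 with median centring and 0.0506 with no filter on dim probes. The 95% interval lay within 2-fold either way for 9 genes. Among them were the strongly expressed glycolytic genes CDC19 (log2 difference -0.33, interval -0.97 to 0.31), TPI1 (-0.26, -0.93 to 0.41), FBA1 (-0.10, -0.65 to 0.44) and GPM1 (-0.02, -0.78 to 0.74). So were the cell wall gene CCW12 (0.08, -0.41 to 0.57) and the metallothionein gene CUP1-1 (0.17, -0.33 to 0.67), whose copies are near-identical. The others were STE5 (0.07, -0.42 to 0.56), REV1 (-0.19, -0.84 to 0.45) and the galactokinase gene GAL1 (-0.18, -0.90 to 0.54), both sugars leaving GAL1 at log2 levels of -2.51 to -1.61. On the spike-in scale none of the 5907 genes tested had an interval within 2-fold, so that scale cannot tell these 9 from other genes.

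With all arrays and no block, the intervals of the remaining 29 genes were too wide to place in either class. Among them, picked for their wide use after the values were seen, TDH3 differed by -0.18 (-1.03 to 0.67), TEF1 by 0.21 (-0.83 to 1.25), TEF2 by 0.03 (-1.40 to 1.46) and ADH1 by 0.43 (-1.15 to 2.01). HXT7 spanned -2.21 to 2.61 and CYC1 0.87 to 4.76, with an adjusted p = 0.145 for CYC1. Without glucose replicate 2 the differences turned to -0.05 for TEF1, -0.38 for TEF2, -0.23 for ADH1 and -1.12 for HXT7, and HXK1 turned from 0.27 to -1.03. Without glucose replicate 2, 8 promoter genes differed at least 2-fold, namely ADH2, ICL1, CYC1 and HSP12 higher and HXK1, HXK2, SSA1 and RPS2 lower in xylose, and 9 were alike, which did not include CDC19, TPI1 or GAL1. The replicate block gave 4 and 20 and the slide block 5 and 20. Both blocks called the enolase gene ENO2, which differed by -1.77 ± 0.67 and had an adjusted p = 0.242 without a block, 0.0344 with the replicate block and 0.0142 with the slide block. At least 2-fold, the slide block also called the aldehyde dehydrogenase gene ALD6 (1.53 ± 0.37, adjusted p = 0.0367). Leaving out xylose replicate 1, 2 or 3 or glucose replicate 1 left 0 promoter genes in the first class, leaving out glucose replicate 3 left 1, and slide 1 alone gave 0. Of promoter genes alike, 4, 5 and 6 were left without xylose replicate 1, 2 or 3 and 4 without glucose replicate 1, while normexp and quantile normalization each gave 17 and slide 1 alone 15. The list's median was -0.09, or -0.33 without glucose replicate 2, and its mean 0.03.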

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

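Keeping outlying spots, averaging xylose replicates 1 and 2 as 1 sample and fitting slide 1 alone were chosen after seeing the data. All 149 called genes kept their sign in every setting that tested them, and a filter on all 6 arrays tested 136 of them. Leaving out, averaging or blocking arrays could not have changed the sign, because the groups of these genes did not overlap. Settings that kept all 6 arrays as separate samples and no block called between 134 and 191 genes, and the called genes that stayed past the threshold numbered 138 with median centring, 138 with quantile normalization, 131 with normexp, 147 in the authors' table, 131 with no filter on dim probes, 136 with the filter on all 6 arrays, 131 with a trended and robust variance and 141 with outlying spots kept. Spike-in centring kept 66 of the 149 and called 25 genes higher and 134 lower. That scale lowers the median of all genes to -0.70, which shifts every gene by about that amount. Its calls among the named genes followed the size of the difference and not a gene's own spread. Calls of single named genes that ended were SET6 and ARG4 with normexp (adjusted p = 0.0521 and 0.0609), ADE3 with normexp (0.0637), COX5A, NUG1 and ARG4 with no filter on dim probes (each 0.0509), and SDH4, COX5A and GPP1 with a trended and robust variance (0.0520, 0.0506 and 0.0525), beside those given with the genes; the cause was not tested. The mean over the probes of a gene was not run, since each gene had 1 probe.

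With the replicate number as a block 310 genes were called, 273 of them at least 2-fold, and 3331 were alike; 137 of the 149 stayed called. Besides the single genes and lists given with their blocked values, the replicate block changed no other call among the genes named by rule and the gene lists. With the slide as a block 690 genes were called, 363 at least 2-fold, 5 promoter genes differed at least 2-fold and 3349 genes were alike; 148 of the 149 stayed called. Averaging xylose replicates 1 and 2 left 12 genes, all at least 2-fold, 0 promoter genes and 824 genes alike. Slide 1 alone left limma with 0 genes, 0 at least 2-fold and 0 promoter genes, at 987 genes with an unadjusted p under 0.05. Both settings have fewer samples. Normexp gave 3360 genes alike and spike-in centring 0. Camera with an estimated correlation called 1 gene list of the 17, a loss that cannot be put down to correlation alone.

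Leaving out 1 array at a time, where a group of 2 is taken to vary like the other group, gave 12 to 682 genes, of which 12 to 548 differed at least 2-fold. The highest count was without glucose replicate 2, which kept all 149, and the others were 12, 12 and 13 without xylose replicate 1, 2 or 3, 28 without glucose replicate 1 and 53 without glucose replicate 3. Genes alike numbered 735 to 2263, the ends being without xylose replicate 1 and without glucose replicate 2. Promoter genes changed at least 2-fold numbered 0 to 8, with 8 without glucose replicate 2 and 1 without glucose replicate 3. The cause of these changes was not tested.

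The named genes that turned direction were all uncalled with all 6 arrays. On the spike-in scale HXT5 stood at -0.30, HXT7 at -0.52, HXT8 at -0.61, HXT9 at -0.34, HXT10 at -0.065, GAL2 at -0.12, XYL2 at -0.35, YJR096W at -0.33 and GCY1 at -0.12, by the shift of that scale. Without 1 array at a time RGT2 spanned -0.52 to 0.13, HXT5 -0.0085 to 0.66, HXT6 -0.26 to 1.88, HXT7 -1.12 to 1.05, HXT8 -0.071 to 0.35, HXT10 -0.076 to 1.48 and HXT12 -0.44 to 0.34; the cause was not tested. Signal over background left 5907 of 6256 probes to test, and a gene dim on every array of a group has only a bound.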

Other observations

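The tests of a strain, of array quality and of a swap for glucose replicate 2, of shared handling of run 3 and of a single array behind the ribosomal pattern were chosen after the results were seen; the others were written before.

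Besides LEU2 and MET17, glucose replicate 2 held other transcripts that the remaining arrays did not, and lacked some that they held. YLR302C, next to MET17, stood at -4.88 and YHL037C at -4.01 in that array alone, both not well above background elsewhere. HIS3 was not well above background on any of the 6 arrays, while YOR203W beside it was well above background on every array except glucose replicate 2, where it lay at -8.55. URA3 stood at 6.35 in glucose replicate 2 against 0.99 to 1.82 on the other arrays, and TRP1 at -4.39 against -0.95 to 0.16.

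Further genes, all picked after their values in glucose replicate 2 were seen and tested as no group, lay outside the range of the other arrays there. The high-affinity zinc transporter gene ZRT1 was at 4.21 against -2.63 to -1.69 elsewhere, ZPS1 at 4.95 against -3.78 to -1.76, ADH4 at 2.63 against -3.79 to -2.78, and VEL1 at 1.76 against -6.62 to -4.85. DAN1 lay at -7.85 in glucose replicate 2 against -4.37 to 1.53 on the other 5 arrays, ANB1 at -3.82 against 0.39 to 3.00, HEM13 at -0.99 against -0.32 to 3.41, and TIR1 at 0.12 against 0.24 to 4.29; all 4 were also lower on the 3 xylose arrays than in glucose replicates 1 and 3. OYE3, an oxidoreductase gene, was at 3.69 in glucose replicate 2 and at 2.02 to 2.25 in xylose, but at -3.14 and -3.09 in glucose replicates 1 and 3.

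Glucose replicate 2 stood apart, with 12 genes off there alone. Poor array quality is argued against by a median coefficient of variation over spots of 4.34%, where the highest of the other arrays had 9.31%. A swap with a xylose array is argued against, since the lowest correlation between xylose arrays was 0.953 and the highest between a xylose array and glucose replicate 1 or 3 was 0.931, which leaves a sample from outside the 6 open. A candidate explanation is another strain under this label: 10 of the 12 genes have a place in the reference and form 6 neighbouring pairs, where 10000 random gene sets gave at most 1. However, the ASP3 copies lie in 1 repeat cluster with YLR156W, YLR159W and YLR161W, so the pairs there may be a single event. Random sets of single genes do not allow for such a cluster. The labels name no strain, and no explanation besides these 3 was tested.

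The 2 arrays of slide 2 deviated from their group means together, at a correlation across genes of 0.707. A wider spread of signal on slide 2 is argued against, since the correlation was 0.685 after quantile normalization, which gives every array 1 distribution. Slide 2 held run 3 of both sugars and no other run, so the slide and shared culture or handling of run 3 cannot be told apart at that value of 0.707.

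As lists, cytosolic ribosomal protein genes were called lower and ribosome biogenesis genes higher in xylose, with 0 of 138 and 1 of 77 genes past the threshold, and neither call held with an estimated correlation (adjusted p = 0.594 and 0.233); on the spike-in scale the biogenesis median was -0.36. Brightness of the probes alone is argued against, since the median of the ribosomal protein genes was -0.46 and the central 95% of 10000 lists of other genes matched on mean level ran from -0.04 to 0.18. Those lists were drawn gene by gene, so their range does not allow for the estimated correlation of 0.70 among the ribosomal protein genes. The mean of the first list less that of the second differed by -0.76 between the sugars, with an exact permutation p = 0.2 (two-sided, smallest possible 0.1). That permutation ran over all splits and did not pair arrays by replicate number. Without 1 array at a time it ran from -1.14 without glucose replicate 2 to -0.53 without glucose replicate 1, which argues against a single array behind its sign, though glucose replicate 2 (2.55) lay within the range of the xylose arrays (2.52 to 2.59) and only glucose replicates 1 and 3 (3.76 and 3.62) lay above it. Time and sugar stay open together, since no sample parts them.

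The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 149 genes and the highest of the others 0, so 1 split reached the real count, and the same held for the 149 at least 2-fold. For gene lists the real split gave 17 and the highest other 22, with 3 splits reaching the real count; for genes alike it gave 2030 and the highest other 2060, with 4 splits reaching it. Of the 10 splits 4 part all 3 pairs of replicate numbers, as the real one does. The other 3 of these gave 0 genes each, with 12, 22 and 14 lists and 2060, 1889 and 2031 genes alike.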
